A study of Homo sapiens with 8 samples.

How the data were processed

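Ribosome footprints and total RNA were sequenced from U2OS cells, a human osteosarcoma line, after siRNA transfection for 48 h, per the labels. The labels name 8 libraries in 4 groups of 2: footprints and total RNA from cells with siRNA against CDK12 (siCDK12) and with control siRNA (siCtrl). Lysis used 100 µg/mL cycloheximide, which holds ribosomes on mRNA, and ribosomal RNA was removed with Ribo-Zero, per the labels' protocols. Nothing in the labels says whether the replicates came from separate cultures, so any spread between them that p-values measure may be technical. FastQC, STAR 2.5.2b, HTSeq and DESeq2 with build hg19 were used, per the submitters' processing notes, which give no roles for them.

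The file analysed is 1 table made by the authors with xtail, a method that tests changes in translation efficiency (TE), the ratio of footprints to total RNA per gene. Per the file headers, the authors gave log2 changes of mRNA and of footprints, log2 TE in each condition, and the log2 change of TE from both xtail pipelines with a final choice between them. The first pipeline compares the mRNA change with the footprint change, and the second compares TE between the conditions. A p-value from each pipeline, a final p-value and an adjusted p-value were also deposited. In all 1233 rows the final p-value was the larger of both, and log2 TE differed between conditions by the footprint change minus the mRNA change, within 1.08e-05. A summary printed beside the table says that 13743 genes entered, that 13724 were tested, and that 613 rose and 620 fell at adjusted p under 0.1. The table lists exactly those genes, with a largest adjusted p of 0.1 after rounding, so a gene absent from it was either not tested or not past that threshold. The Benjamini-Hochberg adjustment recomputed from the final p-values over 13724 genes lay within 1% of the deposited one for all 1233 genes.

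The table holds 0 columns of values per library, so standard errors, replicate values and the depth of each sample are unknown, and no test of libraries was run. Its name holds rep2, which may stand for both replicates or for a single one, so the libraries that entered are unknown. A gene was called at the authors' adjusted p under 0.05. Before the data were examined, 30 gene lists with 968 distinct genes, the tests and the rule for named genes were fixed. The rule names the 10 genes called higher and the 10 called lower with the largest TE change, CDK12, CDK13, CCNK, EIF4EBP1, EIF4E, EIF4G1, MTOR and CHEK1 where measured, and per list up to 4 called members with the largest change. For a list with no called member it names the member with the largest change, as a value. One gene that the rule names is not reported here. A gene outside the rule is said to have been chosen after its values were seen.

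The planned background for the lists was all measured genes, and the truncated table required changes. For calls, all members of a list were taken as tested and set against the 13724 tested genes in two-sided Fisher exact tests, adjusted by Benjamini-Hochberg over all lists and both directions. Members that were not tested make this conservative for an excess of calls. Lists were not matched on expression, which was not given. If their members were easier to call than other genes, an excess could come partly from that. For shifts, the median change of a list with at least 5 listed members was set against 10000 random lists of listed genes (two-sided permutation test, Benjamini-Hochberg over 16 lists for each of TE, mRNA and footprints). The smallest p these lists can give is 0.0002. This second test asks only whether a list stands apart from other genes already selected for a TE change. Counts adjusted over the list alone took unlisted members at the largest possible p, so they are lower bounds. In most lists all listed members pass this, so these counts mostly repeat the listing at adjusted p under 0.1 and are not separate support. Genes are not independent replicates, and these tests describe this table.

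Names were matched to RefSeq (assembly GRCh38.p14), which placed 1229 of the 1233 genes. Because the builds differ, it was used only for names and for which protein-coding genes neighbour each other. The direction of TE was compared between neighbouring listed genes with 10000 permutations of the directions. After seeing that result, lists were also compared with random lists matched on the directions of each gene's listed neighbours within 20 genes, in 5 strata of the share that was lower. A first version of this test, in which 1 neighbour was drawn per member, was dropped because uniform neighbourhoods left it without spread. It had called 9 of 16 lists, among them lists that differed from their neighbours by 1 member.

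Alternatives fixed beforehand were other thresholds, minimum changes, the separate pipelines, centring, other list statistics, matched random lists and limma's cameraPR with preset correlations of 0.01 and 0.05. An estimated correlation needs values per library and was not used. The shift test and the neighbour-matched test were checked on simulated lists drawn from the listed genes. The shift test called 6% of 100 random lists of 10 genes and 48% of lists of 10 lower-TE genes, and 2% and 69% with 15 genes, so it misses many lists of the sizes tested here. The neighbour-matched test called 2% of 200 random lists of 13 genes and 77.5% of lists of 13 lower-TE genes. The Fisher test was checked on simulated counts of independent calls, and called an excess in 2.1% of 1000 unchanged lists of 45 genes. Calls in these data need not be independent, so its rate here may differ.

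A row named by a calendar date in place of a gene symbol was kept in counts and left unnamed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.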

Results

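The series asked how depletion of CDK12, a kinase of the RNA polymerase II C-terminal domain, changes translation in U2OS cells. Ribosome footprints and total RNA were sequenced from cells with siCDK12 and with siCtrl, with 2 libraries in each of 4 groups. Results are given as translation efficiency (TE), the ratio of footprints to mRNA, for siCDK12 over siCtrl. Gene values, their log2 changes and their adjusted p are copied from the authors' deposited table. It gives neither replicate values nor errors, and the depth and the libraries that entered it are unknown. It lists 1233 of 13724 tested genes, those with adjusted p under 0.1.

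The targeted gene was lower at every level. In the authors' deposited table, CDK12 fell by 2.35 in mRNA and by 4.12 in footprints on the log2 scale, 5.08-fold and 17.4-fold. Its TE changed by -1.78 in the authors' deposited table (adjusted p = 0.000346). CHEK1, a kinase of the DNA damage checkpoint, had an mRNA change of -0.39, a footprint change of -1.59 and a TE change of -1.20 in the authors' deposited table (adjusted p = 0.0137). CDK13, CCNK, EIF4EBP1, EIF4E, EIF4G1 and MTOR were not listed, so each was either not tested or not past adjusted p of 0.1.

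TE changed in 600 genes (4.37% of those tested), with 271 higher and 329 lower in siCDK12. The deposited values do not show how libraries were scaled. Changes may thus be relative to other genes, and a change shared by most genes may not appear. The median change was 1.09 among the higher genes, 2.13-fold, and -1.17 among the lower genes, 2.25-fold. Lower genes made up 54.8% of the calls (exact 95% interval 50.8 to 58.9, exact two-sided binomial p = 0.0199). At adjusted p under 0.1 the split was 613 higher to 620 lower (exact p = 0.864), and under 0.01 it was 40 to 66 (exact p = 0.0148). These tests take genes as independent, while neighbouring genes shared directions, so the interval is too narrow and the p-values are too small to show an excess of lower genes.

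Among the 10 genes with the largest rise in TE, MARCH2, a ubiquitin ligase, led with 3.50 in the authors' deposited table (adjusted p = 0.00727). The chemokine CCL3 rose by 2.79 in TE in the authors' deposited table, on top of an mRNA change of 3.87 (adjusted p = 0.0145). Both metal-binding metallothioneins among these genes rose, MT2A by 2.12 (adjusted p = 8.56e-09) and MT1X by 1.72 (adjusted p = 0.00163) in the authors' deposited table. The others in the authors' deposited table were FBXL8 (2.09), the acute phase gene SAA2 (1.96), NOTCH2NL (1.83), ZNF580 (1.78), the repressor HIC2 (1.76) and the potassium channel KCNQ3 (1.74). MT, SAA2 and NOTCH2NL sequences have close paralogs, and their values are uncertain where reads could be split among copies.

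The largest fall was that of RPL17-C18orf32, a readthrough locus that shares reads with both of its parent genes, at -4.43 in the authors' deposited table, with 3.90 in mRNA and -0.52 in footprints (adjusted p = 0.0137). LLPH, a nucleolar protein gene, followed with -3.70 in the authors' deposited table (adjusted p = 0.000332). HNRNPA1, an RNA-binding splicing regulator with many pseudogenes, changed by -3.19 in the authors' deposited table, with -3.55 in footprints and -0.37 in mRNA (adjusted p = 8.56e-09). Below them in the authors' deposited table stood C9orf85 (-3.03), WBP5 (-2.46), the ribosome assembly factor NSA2 (-2.31), the centriole gene CEP83 (-2.11), ZNF26 (-2.08), DBF4 (-2.04), a subunit of a replication kinase, and MNS1 (-2.03).

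In most called genes the footprint change was larger than the mRNA change. Among the 271 genes with higher TE, footprints were higher in 253, with a median of 1.01, and mRNA was lower in 151, with a median of -0.13. In 18 of the 271 footprints were lower, and mRNA was lower still. Of the 329 genes with lower TE, footprints were lower in 320, with a median of -0.93. Their mRNA was higher in 214 and lower in 115, with a median of 0.27. In 9 of the 329 footprints were higher, and mRNA was higher still. The footprint change exceeded the mRNA change in size in 213 of the higher and 253 of the lower genes. Across the 1233 listed genes, footprint and mRNA changes had a Pearson r of 0.482 and a Spearman rho of 0.358. Genes without a TE change are not listed, which lowers this r, and genes are not independent replicates. Within the calls of one direction, r was 0.941 for higher and 0.873 for lower genes, values raised by the selection, since it leaves a nearly constant difference between both changes.

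**Figure D1:**
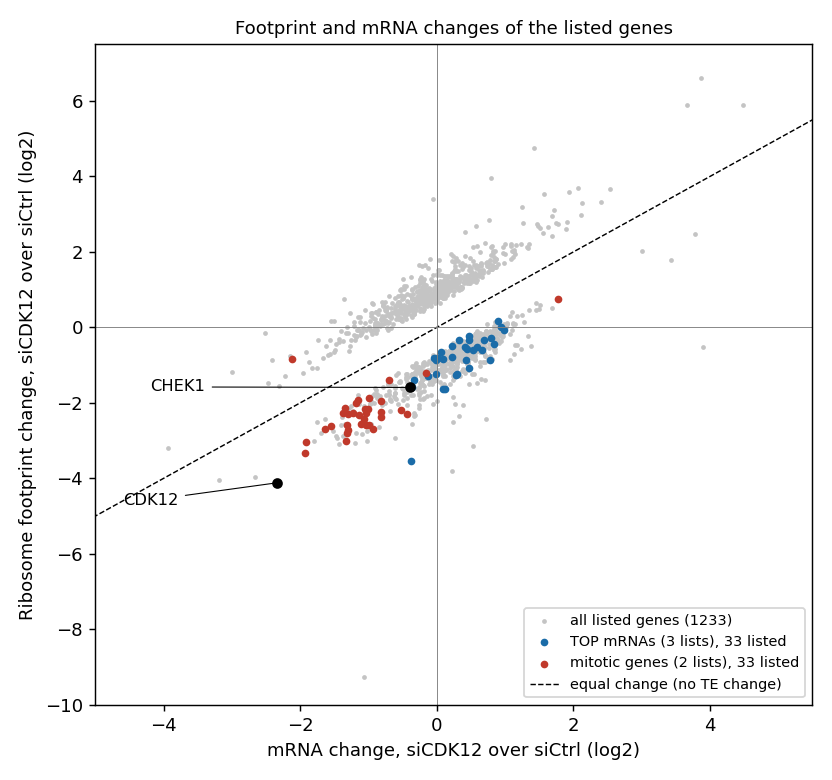
Log2 change of ribosome footprints (vertical axis) against log2 change of mRNA (horizontal axis), siCDK12 over siCtrl, one point per gene for the 1233 listed genes, from the authors' deposited table. Genes with TOP mRNAs (33 listed) lie below the dashed line of equal change and mostly at positive mRNA changes, and mitotic genes (33 listed) lie lower and further left, with 32 of them below the line.

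The direction of the TE change went with the place of a gene in the genome. Of 119 pairs of listed genes that are adjacent in the annotation, 102 had one direction, 85.7% (bootstrap 95% interval 79.0 to 91.6), against 50% with permuted directions (one-sided permutation p = 0.0001, the smallest possible). Without pairs that share the start of a name or overlap, it was 84.7% of 98 pairs. In the same 98 pairs, the direction of the footprint change was shared in 79.6% and that of the mRNA change in 64.3%. The share for TE was 84.1% at 2 to 5 genes apart, 84.2% at 6 to 20, 76.8% at 21 to 50, 69.2% at 51 to 100 and 59.4% in the furthest range taken. The 16 gene lists with at least 5 listed members are therefore given below with the share of lower genes among members with listed neighbours and in random lists matched on the directions of those neighbours, an alternative chosen after seeing the data.

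Of the 30 lists, 8 passed Fisher's exact test for more genes with lower TE than the tested genes as a whole, and 1 passed for higher TE. Against random lists of genes that were themselves listed, the median TE change stood apart in 1 of 16 lists, the kinetochore list. Against neighbour-matched lists, 3 of 16 lists differed in direction. Some lists with few members could not have passed this test, as given below.

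Part of the genes whose mRNAs begin with a terminal oligopyrimidine tract (TOP), which couples translation to growth signalling, had lower TE. In the 3 lists of such mRNAs, with 105 genes, 33 were listed, all of them lower, and 25 were called. Of the 25, 21 had higher and 4 had lower mRNA, with medians of -1.13 for TE, 0.42 for mRNA and -0.80 for footprints. For large ribosomal subunit proteins, 11 of 47 were called lower and 0 higher (Fisher's exact test, adjusted p = 3.08e-07), and at least 13 were lower when adjusted over the list alone. In the authors' deposited table, TE changed by -1.75 for RPL32, -1.55 for RPL5, -1.53 for RPL30 and -1.24 for RPL27. For TOP translation factors and other TOP mRNAs, 12 of 25 were called lower and 0 higher (Fisher's exact test, adjusted p = 6.97e-12), and at least 16 when adjusted over the list alone. Besides HNRNPA1, the authors' deposited table gave -1.72 for the histone chaperone NAP1L1, -1.63 for the import receptor IPO7 and -1.29 for the initiation factor subunit EIF3H. The median mRNA change of the 16 listed members, 0.62, was higher than that of random lists (permutation test, adjusted p = 0.004).

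Small ribosomal subunit proteins did not pass, with 2 of 33 called lower (Fisher's exact test, adjusted p = 0.646). The authors' deposited table gave -1.52 for RPS24 and -0.93 for RPS18. At least 4 were lower when adjusted over the list alone. Neighbour-matched lists held 49.2% lower genes where 100% of 13 large subunit members with listed neighbours were lower (permutation test, adjusted p = 0.0032). They held 70.7% where 100% of 14 such TOP factor members were lower (permutation test, adjusted p = 0.0048). The median TE change of neither list stood apart from random lists of listed genes (permutation test, adjusted p = 0.103 for the large subunit and 0.0928 for the TOP factors). This depended on the test, since both lists passed cameraPR at a correlation of 0.01 (adjusted p = 0.00703 and 0.00137). Ribosomal protein and EEF1A1 genes have many pseudogenes, so their levels are uncertain.

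Part of the mitotic genes had lower TE beside lower mRNA. In both lists together, with 94 genes, 33 were listed, 32 of them lower. All 19 genes called lower had lower mRNA, with medians of -1.43 for TE, -1.07 for mRNA and -2.56 for footprints. In the kinetochore and spindle checkpoint list, 9 of 45 were called lower and 1 higher (Fisher's exact test, adjusted p = 1.46e-05), and at least 18 were lower and 1 higher when adjusted over the list alone. Comparing only directions among called genes, this list did not pass (Fisher's exact test, adjusted p = 0.17). The authors' deposited table gave TE changes of -1.78 for CENPL, -1.67 for the motor gene CENPE and -1.60 for the cohesin protector SGOL2. The member called higher was CENPM, chosen after its value was seen. It had 1.28 in TE, -2.12 in mRNA and -0.85 in footprints in the authors' deposited table. The median TE change of the 19 listed members was -1.18 (permutation test, adjusted p = 0.0224), and their median mRNA change was -1.06 (permutation test, adjusted p = 0.0016).

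Among mitotic kinases, spindle and cytokinesis genes, 10 of 49 were called lower and 0 higher (Fisher's exact test, adjusted p = 3.92e-06), and at least 14 when adjusted over the list alone. The kinesins KIF15 (-1.68) and KIF20B (-1.43) and the spindle genes CKAP2 (-1.57) and HMMR (-1.45) had the largest falls in the authors' deposited table. The median mRNA change of the 14 listed members was -1.23 (permutation test, adjusted p = 0.0016), while their median TE change, -1.14, did not stand apart from other listed genes (permutation test, adjusted p = 0.0784). For TE the list did pass cameraPR at a correlation of 0.01 (adjusted p = 0.00333). Neighbour-matched lists held 67.1% lower genes against 93.8% of 16 kinetochore members with listed neighbours (permutation test, adjusted p = 0.0192). For the spindle list these shares were 79.9% and 100% of 13 (permutation test, adjusted p = 0.0964), and no larger share was possible.

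Genes for chromosome structure, centrosomes and DNA replication also held more lower genes than the tested genes as a whole. Condensin and cohesin had 5 of 21 called lower (Fisher's exact test, adjusted p = 0.00137), and at least 7 when adjusted over the list alone. The authors' deposited table gave -1.72 for SMC4, -1.38 for SMC3, -1.22 for NIPBL and -1.20 for SMC2. Centrosome and centriole genes had 6 of 42 called lower (Fisher's exact test, adjusted p = 0.00459), and at least 10 when adjusted over the list alone. CEP63 (-2.01), CEP135 (-1.52), AKAP9 (-1.25) and CEP152 (-1.19) led in the authors' deposited table. DNA replication had 5 of 49 called lower (Fisher's exact test, adjusted p = 0.0412), and when adjusted over the list alone at least 10 lower and 1 higher. Besides DBF4, these were topoisomerase TOP2A (-1.22), ORC4 (-1.14) and PRIM1 (-1.01) in the authors' deposited table, and RFC1, named after its value was seen. The median mRNA change of the 11 listed replication genes was -0.71 (permutation test, adjusted p = 0.0147). Of condensin and cohesin genes with listed neighbours, 100% of 7 were lower, against 80% in neighbour-matched lists (permutation test, adjusted p = 0.52). For the centrosome it was 100% of 7 against 85.9% (permutation test, adjusted p = 0.799). For replication it was 90.9% of 11 against 62.4% (permutation test, adjusted p = 0.0624). The condensin and centrosome lists could not have passed for an excess of lower genes, since the draws also reached 100%.

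DNA repair lists did not pass at this threshold. Homologous recombination and Fanconi anaemia genes, often studied in CDK12 loss, had 3 of 38 called lower and 0 higher (Fisher's exact test, adjusted p = 0.311), and at least 6 lower when adjusted over the list alone. The authors' deposited table gave -1.31 for RAD50, -1.24 for BARD1, with -1.52 in mRNA, and -1.05 for NBN. DNA damage signalling had 3 of 29 called lower and 1 higher (Fisher's exact test, adjusted p = 0.172 for lower), and at least 6 lower and 1 higher when adjusted over the list alone. Next to CHEK1, the authors' deposited table gave -1.78 for the deubiquitinase USP1, -1.33 for the kinase ATM and 1.27 for the histone gene H2AFX. H2AFX had -1.92 in mRNA and -0.65 in footprints in the authors' deposited table. In the list of CDK12 and cyclin K, CDK12 was the called gene among 9 members (Fisher's exact test, adjusted p = 0.646), and at least 2 were lower when adjusted over the list alone. Of recombination genes with listed neighbours, 100% of 5 were lower, against 55.3% in neighbour-matched lists (permutation test, adjusted p = 0.0964). For damage signalling it was 83.3% of 6 against 66.8% (permutation test, adjusted p = 0.749). At adjusted p under 0.1 the recombination and the damage list passed (Fisher's exact test, adjusted p = 0.0286 and 0.00809).

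Aminoacyl-tRNA synthetases, which charge tRNAs, had 4 of 23 called lower and 0 higher (Fisher's exact test, adjusted p = 0.0172), and at least 5 when adjusted over the list alone. These were RARS (-1.23), EPRS (-1.03), DARS (-0.86) and KARS (-0.80) in the authors' deposited table. Nuclear-encoded genes of the mitochondrial respiratory chain had 6 of 73 called higher (Fisher's exact test, adjusted p = 0.0237) and 4 called lower (adjusted p = 0.42). Adjusted over the list alone, at least 10 were higher and 4 lower. COX6A1 (1.56), COX8A (1.38) and UQCR11 (1.37) were higher and NDUFC2 (-1.41) was lower in the authors' deposited table. Of synthetases with listed neighbours, 100% of 5 were lower, against 78.1% in neighbour-matched lists (permutation test, adjusted p = 0.693). The draws also reached 100%, so this list could not have passed for an excess of lower genes. For the respiratory chain it was 30.8% of 13 against 43.6% (permutation test, adjusted p = 0.52).

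The mitochondrial ribosome list had 3 of 78 called lower and 1 higher, namely MRPS18C (-1.26), MRPS9 (-0.92), MRPS27 (-0.87) and MRPL4 (0.93) in the authors' deposited table. Cytosolic chaperones had 3 of 25 called lower (Fisher's exact test, adjusted p = 0.128), with CCT8 (-1.01), HSP90AA1 (-0.90) and DNAJA1 (-0.38 in footprints with 0.62 in mRNA) in the authors' deposited table. Proteasome genes had 2 of 35 called lower, PSMA6 (-1.21) and PSMA3 (-1.19) in the authors' deposited table. Adjusted over the list alone, at least 7, 6 and 3 members of these lists were lower and 4, 0 and 0 higher. The splicing list had 1 of 41 called lower, HNRNPDL (-1.24), and 2 higher, SRSF2 (1.03) and SF3B4 (0.99), in the authors' deposited table. One gene was called lower in each of the glycolysis list (LDHB, -0.92), the endoplasmic reticulum chaperone list (SEC61G, -1.38) and the interferon list (DDX58, -0.98) in the authors' deposited table. DDX58 had 1.44 in mRNA and 0.46 in footprints in the authors' deposited table. Of members with listed neighbours, 66.7% of 12 were lower for the mitochondrial ribosome, 100% of 5 for the chaperones and 60% of 5 for splicing. Neighbour-matched lists held 63.5%, 54.6% and 54.0% lower genes (permutation test, adjusted p = 1, 0.0964 and 1). Adjusted over the list alone, at least 1 gene was lower in each of the splicing, glycolysis, reticulum and interferon lists, and 2, 3, 0 and 1 were higher. With calls at adjusted p under 0.05, none of these lists passed Fisher's exact test in either direction. With calls under 0.1 the cytosolic chaperones did, with 6 lower (Fisher's exact test, adjusted p = 0.00469).

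**Figure D2:**
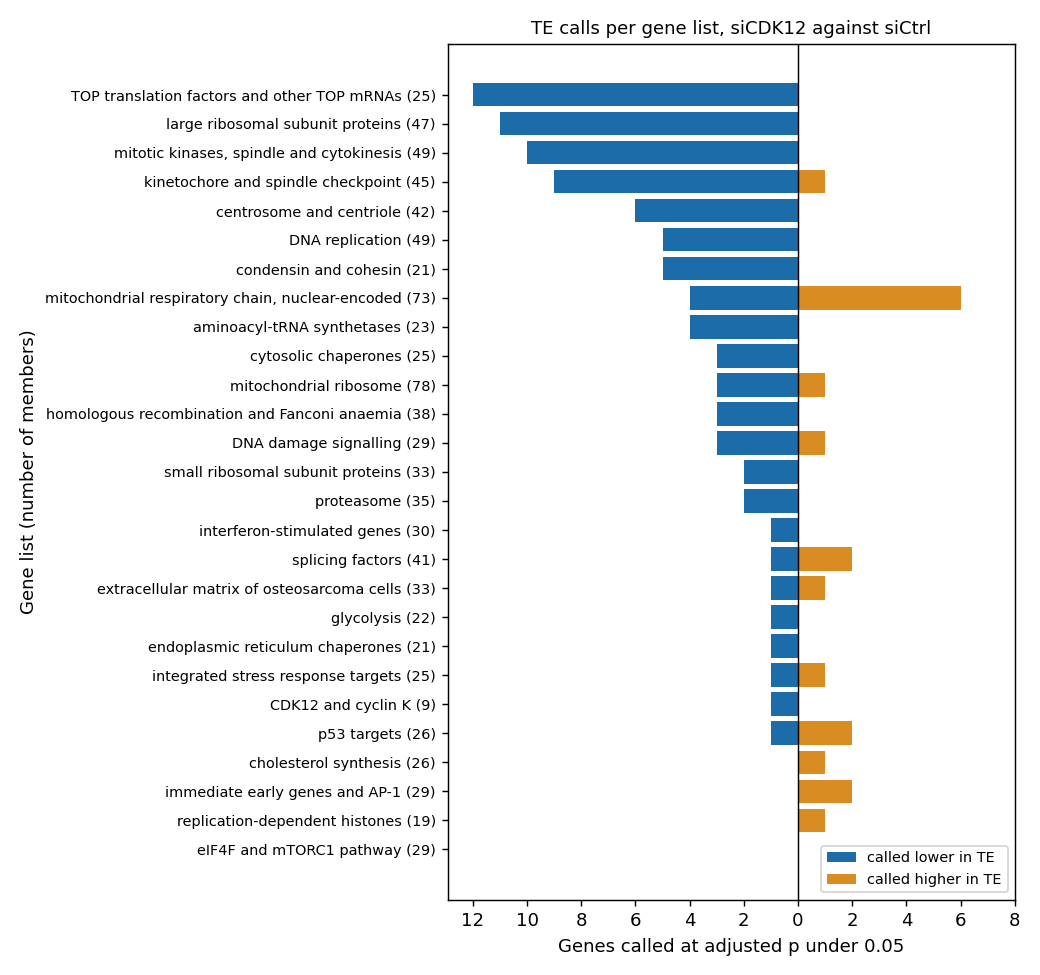
Number of genes called at adjusted p under 0.05 (horizontal axis) in each gene list with a listed member (vertical axis, number of members in brackets), called lower in TE to the left and higher to the right. TOP translation factors (12 lower, 0 higher) and large ribosomal subunit proteins (11 lower, 0 higher) have the longest bars, and the respiratory chain has 6 higher and 4 lower.

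Targets of p53 had 2 of 26 called higher and 1 lower (Fisher's exact test, adjusted p = 0.42 for higher). The stress cytokine GDF15 rose by 1.42 in TE, with 4.48 in mRNA and 5.90 in footprints, and BTG2 by 0.96, while CCNG1 was at -1.21 in the authors' deposited table. At adjusted p under 0.1, 7 were higher and 1 lower (Fisher's exact test, adjusted p = 0.000804), as were at least 7 and 1 when adjusted over the list alone. The median mRNA change of the listed p53 targets was 0.89 (permutation test, adjusted p = 0.00213) and that of footprints 1.80 (permutation test, adjusted p = 0.0032). Immediate early genes had 2 of 29 called higher, IER3 (1.17) and FOSL2 (0.98) in the authors' deposited table, and 6 at adjusted p under 0.1 (Fisher's exact test, adjusted p = 0.446 and 0.00809). FOSL2 had -1.10 in mRNA and -0.12 in footprints in the authors' deposited table. At least 6 immediate early genes were higher and 0 lower when adjusted over the list alone. Of p53 targets with listed neighbours, 12.5% of 8 were lower, against 31.6% in neighbour-matched lists (permutation test, adjusted p = 0.416). For immediate early genes it was 0% of 6 against 25.5% (permutation test, adjusted p = 0.264). The draws also reached 0%, so the immediate early list could not have passed for an excess of higher genes.

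Among other lists, cholesterol synthesis (DHCR7, 0.84), replication-dependent histones (HIST2H2AC, 0.94, with -1.87 in mRNA) and the extracellular matrix (TIMP1, 0.77) each had 1 gene called higher in the authors' deposited table. HIST2H2AC had -0.93 in footprints in the authors' deposited table. ITGB1 of the matrix list was called lower at -1.08 in the authors' deposited table. Integrated stress response targets held SLC7A5 (0.97) and EPRS, 1 called each way, in the authors' deposited table. SLC7A5 had -1.04 in mRNA and -0.06 in footprints in the authors' deposited table. In the list of eIF4F and the mTORC1 pathway, 0 of 29 genes were called. Its only listed member was SESN2, at 0.85 in the authors' deposited table (adjusted p = 0.0587). The TE changes of its other members are unknown, since each was either not tested or not past adjusted p of 0.1. Mitochondrially encoded genes, epithelial markers and haematopoietic markers had 0 listed members. Adjusted over the list alone, at least 1 gene was higher and 0 lower for cholesterol synthesis and histones, 2 and 1 for the matrix, 2 and 2 for the stress response, and 0 for the others. None of these lists passed Fisher's exact test.

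Across the listed genes, the TE change had a Pearson r of 0.228 and a Spearman rho of 0.228 with mean log2 TE of both conditions. In 10 bins of mean log2 TE, the share of lower genes was 58.9% in the lowest bin, 57.7% in the 7th and 12.9% in the highest. With control TE in place of the mean, r was -0.296, so the direction of this relation depended on that choice, and the error of control TE enters both of its axes.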

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

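The neighbour-matched lists, the direction test among called genes, the random lists with the same TE directions, the adjustment computed over all genes tested and the other thresholds for the split were chosen after the results were seen. Nothing here tests libraries, since the table gives none. No paired analysis was possible because the columns carry no replicates, and for the same reason DESeq2, the filter on counts, the replicate block and leaving out each replicate were not run.

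Calls of higher and lower TE numbered 40 and 66 at adjusted p under 0.01, and 613 and 620 at 0.1. Adjusting over the listed genes alone also gave 613 and 620, since it counts fewer tests. The first pipeline, adjusted over all genes tested, gave at least 604 and 618, and the second at least 281 and 335, since neither p is above the final one. A change of at least 1 left 182 and 252, and removal of extreme TE 237 and 305. Centring cannot move these calls, and a minimum change of 0.58 lies below the smallest change listed. The split had an exact p of 0.864 at the threshold of 0.1 and of 0.0148 at 0.01, with 62.3% lower, both with genes taken as independent. All 90 named genes kept their direction in both pipelines, with differences up to 0.05. The smallest change listed was 0.61, so differences of this size could not reverse a direction, and this is not separate support.

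At adjusted p under 0.01, Fisher's exact test no longer called centrosome (adjusted p = 0.888), replication (0.903), synthetase (0.700) or respiratory chain genes (0.888), with fewer genes counted. At 0.1 it also called homologous recombination (0.0286), DNA damage (0.00809) and chaperone genes (0.00469) lower, and p53 targets (0.000804) and immediate early genes (0.00809) higher. Comparing only directions among called genes, Fisher's exact test did not pass for kinetochore (adjusted p = 0.17), condensin (0.25), centrosome (0.181), replication (0.25), synthetase (0.425) or respiratory chain genes (0.778). All called condensin, centrosome, replication and synthetase genes were lower, so no smaller p for lower genes was possible. Before adjustment, Fisher's exact test gave p = 0.0673 for condensin and for replication and 0.131 for synthetases. These lists had too few calls to pass. Neighbour-matched permutation tests did not pass for spindle (adjusted p = 0.0964), condensin (0.52), centrosome (0.799), replication (0.0624), synthetase (0.693) or respiratory chain genes (0.52). In the condensin, centrosome and synthetase lists every member with listed neighbours was lower, and the 95% range of the draws reached 100%. These lists could not have passed for an excess of lower genes. Every such spindle member was lower too, so its p was the smallest possible for lower genes. The large ribosomal subunit and TOP factor lists passed under each of these. A list that could not have passed gives no evidence against a shared direction, and the cause of the other losses was not tested further.

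For the TE shift of lists, 87 of 112 comparisons stayed on their side of the threshold, among them all with either pipeline or with lists matched on mean TE. Agreement between the pipelines is not separate support, since the final value is taken from them. Taking the mean, the permutation test also called large subunit (adjusted p = 0.00400), TOP factor (0.0016), spindle (0.00213), condensin (0.00800), centrosome (0.00512), replication (0.0284) and immediate early genes (0.0119). The share below the median called large subunit (permutation test, adjusted p = 0.0016), TOP factor (0.00107), spindle (0.00107), condensin (0.0416) and centrosome genes (0.0096). The kinetochore list stayed past in each. With cameraPR at a correlation of 0.01, the calls besides it were large subunit (adjusted p = 0.00703), TOP factor (0.00137), spindle (0.00333), condensin (0.0109), centrosome (0.00978), replication (0.0457) and immediate early genes (0.0251). At 0.05 they were large subunit (adjusted p = 0.027), TOP factor (0.0201), spindle (0.0243), condensin (0.027), centrosome (0.027) and immediate early genes (0.0451). Listed genes fall into a higher and a lower group with a gap between, so a median inside the lower group moves little, and means and shares count members on each side.

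With random lists of the same TE directions, the footprint shift was no longer past the threshold for condensin (permutation test, adjusted p = 0.304), centrosome (0.372), homologous recombination (0.36), DNA damage (0.128) and replication genes (0.0941), and passed for TOP factors (0.0296). All 16 mRNA shifts kept their side. The relation of the TE change to TE reversed to r of -0.296 with control TE on the horizontal axis, whose error enters the change with opposite sign.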

Other observations

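Families were sought by the start of the gene symbol, after the table had been seen, and some lie partly in the lists, with 26 families of at least 5 listed genes tested. Of these, 5 passed and 21 did not, among them MRPL (3 lower, 3 higher), ZNF (13 and 9), SMC (5 and 0), KIF (7 and 1) and FBXL (0 and 5). Solute carriers (SLC), which move nutrients and ions across membranes, had 26 higher and 1 lower gene (Fisher's exact test, adjusted p = 3.82e-06). Genes named TMEM, for transmembrane proteins, had 21 higher and 1 lower (Fisher's exact test, adjusted p = 5.71e-05). Initiation factor genes (EIF) had 0 higher and 14 lower (Fisher's exact test, adjusted p = 0.000739), and centrosomal CEP genes 0 and 12 (Fisher's exact test, adjusted p = 0.00241). The RPL genes had 0 and 15, with the readthrough locus RPL17-C18orf32 counted among them (Fisher's exact test, adjusted p = 0.000487). Many EIF, CEP and RPL genes are members of the lists above, so these counts are not independent of them. These counts include genes between adjusted p of 0.05 and 0.1. EIF1, which guides start codon choice, was chosen after its value was seen. In the authors' deposited table it changed by -1.95 in TE with -0.01 in mRNA (adjusted p = 0.000142).

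Further single genes were chosen after their values were seen, without a test of a group. In the authors' deposited table, MT1E changed by 0.92, the iron storage gene FTL by 1.55 and the haem oxygenase gene HMOX1 by 0.92, the last with 2.41 in mRNA. HMGN2, not called (adjusted p = 0.0577), had a footprint change of -9.28 but a final TE change of -3.64 in the authors' deposited table, 1 of 8 genes whose final value lay over 0.1 from the plain difference.

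The test of neighbouring genes was written before its result was seen, and the other tests below after. In some gene families the listed genes shared a direction of the TE change. Genes near each other share base composition, and 85.7% of adjacent pairs had one direction, a result that regional base composition predicts and that a difference in base bias between libraries may also give, though composition itself was not measured. For TOP mRNAs, 100% of the 31 members with listed neighbours were lower, against 59.9% in neighbour-matched lists (one-sided permutation p = 0.0001, the smallest possible). The directions of neighbours, as matched, thus did not account for the whole share. The strata are coarse, and where all neighbours were lower, 86.4% of genes were lower. A regional effect that the strata miss therefore stays open. Each gene's own composition stays open. An error in total RNA stays open too. Of the 25 called, 21 had higher mRNA, the direction such an error gives, as had 214 of all 329 genes called lower. Footprints, which it leaves alone, were lower in 24 of the 25. They were also lower in 320 of the 329, which were selected for lower TE, so this count cannot decide.

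Of the 33 listed mitotic genes, 32 were lower in TE, and 31 of these were lower in mRNA. An error in total RNA moves mRNA and TE in opposite directions and leaves footprints alone, so by itself it does not give lower mRNA with lower TE, and medians of the 19 called lower were -1.07 for mRNA and -2.56 for footprints. A real fall in mRNA that total RNA under-reported would still lower TE, and this stays open, since the table holds no other measure of mRNA. Among members with listed neighbours, 96.6% of 29 were lower in TE, against 72.9% in neighbour-matched lists (one-sided permutation p = 0.0001, the smallest possible). The directions of neighbours, as matched, thus did not account for the whole share in the pooled group. Of its lists, the kinetochore list passed alone and the spindle list did not (permutation test, adjusted p = 0.0192 and 0.0964). All 13 spindle members with listed neighbours were lower, so no smaller p for lower genes was possible there. A regional effect that the coarse strata miss stays open here too. No biological explanation was tested, and members absent from the table are not covered.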
